A study of Sporobolus alterniflorus with 18 samples.

How the data were processed

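Total RNA of the third expanded leaf from 18 pools was labelled with Cy3 and hybridised to one-colour Agilent arrays of 60-base probes, per the labels' protocols. Each pool holds RNA of 3 plants, and the 9 plants of a population were assigned to its 3 pools at random, per the series' design text. Populations were taken from the sample titles, and pool numbers run from 1 to 18 without repeats, so no pools are paired across populations. Oiled and not oiled Grand Isle populations with the same letter were treated as 1 site, which the titles do not state. Pools hold different plants, but the pools of 1 population come from 1 place, and p-values measure the spread between pools.

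The deposited scanner files hold spot intensity on a linear scale, made by Feature Extraction 10.1.1.1, per the file headers. The submitters' processing notes name Agilent Feature Extraction 9.1, and which of the versions made the authors' value table is not given in the sources used here. The background-corrected spot signal (gProcessedSignal) was used, and per the file headers the mean and local background signal of each spot (gMeanSignal, gBGMedianSignal) served the normexp alternative. The authors also deposited a table of log2 values, one column per sample. From the values, 16 of its 18 columns equal the median over a probe's spots of the log2 signal, minus 1 constant per array. The match is within 1e-06 for 96% to 97.7% of the probes with a value. The column medians range from -1.65 to -1.54 and 23216 cells are empty. The values are not centred per probe. What removed the empty cells is not given in the sources used here. Of the 16 columns, 1 equals the array listed for its own sample and 15 equal the array listed for another sample. The scanner files were therefore the source of the main values, with each file's sample as GEO lists it, and the value table was used as an alternative.

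The 1417 control spots were left out. The 43803 other spots of each array belong to 17049 probes, 9705 with 3 spots and 7344 with 2. The log2 of each signal was taken minus the array's 75th percentile, and spots of a probe were averaged without outlier spots where another remained. The median SD between spots of a probe was 0.078 to 0.088 on the log2 scale. Probes well above background in all 3 pools of at least 1 population were tested, which left 14988 and removed 2061; 13448 probes were well above background on all 18 arrays. The number of arrays limits the precision.

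Limma 3.58.1 in R 4.3.3 fitted 6 population means to all 18 pools, with 12 residual degrees of freedom, 2.61 prior degrees of freedom and a median residual SD of 0.21. The contrasts were the mean of the 3 within-site oiled-minus-not-oiled differences, each within-site difference, the moderated F test of the differences between sites, Bay Saint Louis minus Grand Isle, and Grand Isle site A minus site B. Benjamini-Hochberg adjusted p under 0.05 was the threshold in each contrast. The contrasts other than the F test were tested two-sided. Where a probe was well above background on no array of a population on the dimmer side, a limited fold was computed. On either side, a population without such an array took, per array, the higher of its own signal and the lowest signal well above background. Dim arrays of other populations kept their own signal. It is called a lower bound only where no such dim array lies on the dimmer side and no raised population on the brighter side. Distances and principal components used the tested probes.

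Every probe's description in the files reads as unknown, and no table of gene names was used here. The 32 gene lists fixed before the data were examined therefore could not be matched to probes, and neither the gene list test nor its alternatives were run. For this case the rule fixed beforehand names the 2 highest and 2 lowest probes of each contrast. It was applied to probes past the threshold; for oil over 3 sites only to those with the same sign at the 3 sites, and for the F test to the 4 largest F among probes that passed at 2 sites in opposite directions, both taken from the rule for annotated genes. Without the condition on sign CUST_10417_PI428634872 would have taken the place of CUST_1639_PI428634872.

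The array holds 16953 distinct probe sequences. Probes were aligned to each other with blastn 2.17.0, and 98 tested pairs with identical sequence had oil differences that correlated at r = 0.993. Among 308 pairs aligned over fewer than 50 bases r was 0.593. The oil difference had a Spearman correlation of -0.14 with GC content across probes, and its median over all probes was -0.008.

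The fits were tested on simulated data for 14988 probes, with independent normal noise and each probe's residual SD shared by all populations. In the data the median SD between pools ran from 0.088 to 0.269 over the populations. False calls under such unequal spread were therefore not measured. For oil over 3 sites, 76%, 90%, 98% and 100% of probes changed 1.5-, 2-, 4- and 8-fold were recovered, with 8 false calls. With slide as a fixed term these shares were 0%, 14%, 52% and 64%. Data were also simulated 20 times from the fitted means without any slide effect, to count what the additive fit with slide then calls. Only slide 3 held both oil states. On population means the shares recovered were 20%, 70%, 94% and 100%, for simulated effects shared by all 3 sites and without other differences between populations. With no effect and no difference between populations simulated, 0 probes were called in each of the 7 tests.

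The 18 arrays lay on 5 slides, each scanned once, so slide and scan cannot be told apart. Slide 1 held the oiled pools of Grand Isle site A and 1 of site B, slide 2 held 2 oiled pools of site B and 2 of Bay Saint Louis, and slide 3 held 1 oiled pool of Bay Saint Louis with the not oiled pools of site A. Slide 4 held the not oiled pools of site B and 1 of Bay Saint Louis, and slide 5 held 2 not oiled pools of Bay Saint Louis. Alternatives fixed before the data were examined were normexp with an offset of 50, quantile normalization, median centring, the authors' values, no filter and a strict filter on dim probes, slide as a random block, array position as a covariate, array weights, and a trended robust variance prior. Others were fits on only the populations compared, leaving out each pool in turn, and, for oil over 3 sites, slide as a fixed block, no interaction, population means, and a test against a 1.5-fold change. Alternatives chosen after seeing the data are named in the closing section.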

Results

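Leaf RNA of the salt marsh grass Sporobolus alterniflorus (formerly Spartina alterniflora, smooth cordgrass) was measured on custom one-colour arrays after plants had been collected in the field and frozen at once. The labels name 6 populations in places reached by the Deepwater Horizon oil spill. At Grand Isle in Louisiana they give oiled sites A and B and not oiled sites A and B. At Bay Saint Louis in Mississippi they give 1 oiled and 1 not oiled population. Grand Isle populations with the same letter were paired here as 1 site, which gave 3 sites. The titles do not state that such a pair lies in 1 place, so comparisons within and between the Grand Isle sites rest on this pairing. In each population 9 plants were combined at random into 3 RNA pools of 3 plants, so 18 pools were hybridised, 9 of them oiled. The third expanded leaf was sampled. Each array carried 17049 probes of 60 bases, of which 14988 were well above background in all 3 pools of at least 1 population and were tested. The 75th percentile of signal ranged from 474.7 to 1187.7 over the 18 arrays, between 82.8% and 87.8% of the probes were well above background on each array, and no spot was saturated. The number of arrays limits the precision. Probes are given by their identifiers, because the files do not pair them with genes. Their positions in a genome are not given in the sources used here.

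The first question was how the 6 populations relate to each other in leaf expression. The 2 not oiled Grand Isle populations stood apart from the other 4. On the first principal component, which held 39.1% of the variance, their pools lay at 52.5 ± 2.7 (SD, n = 3) at site A and 71.8 ± 0.8 (SD, n = 3) at site B. The oiled pools lay at -33.3 ± 9.4 at Grand Isle site A, -33.7 ± 4.7 at site B and -23.9 ± 2.4 at Bay Saint Louis (SD, n = 3 each). The not oiled Bay Saint Louis pools, at -33.4 ± 2.1 (SD, n = 3), lay among the oiled ones on this component. They were set apart on the second component, which held 21.6% of the variance, at -62 ± 2 (SD, n = 3).

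**Figure D1:**
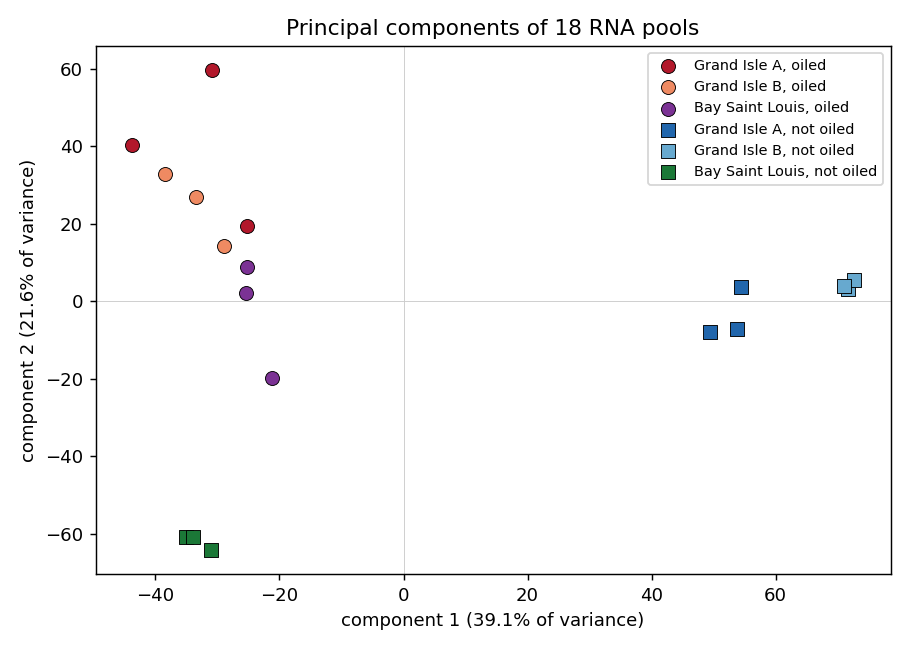
First and second principal components (percent of variance on each axis) of log2 signal in 18 RNA pools; each point is 1 pool, circles are oiled and squares not oiled populations. The 6 pools of the not oiled Grand Isle populations lie to the right, with means of 52.5 and 71.8 on the first component, and the not oiled Bay Saint Louis pools lie at the bottom, with a mean of -62 on the second.

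Distances between pools, as the root mean square log2 difference over tested probes, gave the same arrangement. The not oiled populations of Grand Isle lay 0.63 from each other and 0.981 and 1.071 from the not oiled population of Bay Saint Louis. The oiled populations lay 0.625, 0.79 and 0.656 from each other. The mean distance between sites was 0.69 for oiled and 0.894 for not oiled populations, and 4 of the 8 assignments of the oil label within sites gave a difference at least as large (exact permutation test, two-sided p = 0.5, smallest possible 0.25), so the design could not reach a p under 0.05 for this difference. Oil accounted for 27.5% of the sum of squares, site for 25.6%, the site by oil term for 25% and the spread between pools of a population for 21.9%. Within the oiled population of Grand Isle site A the pools were 0.693 apart on average, farther than that population lay from the oiled population of site B.

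**Figure D2:**
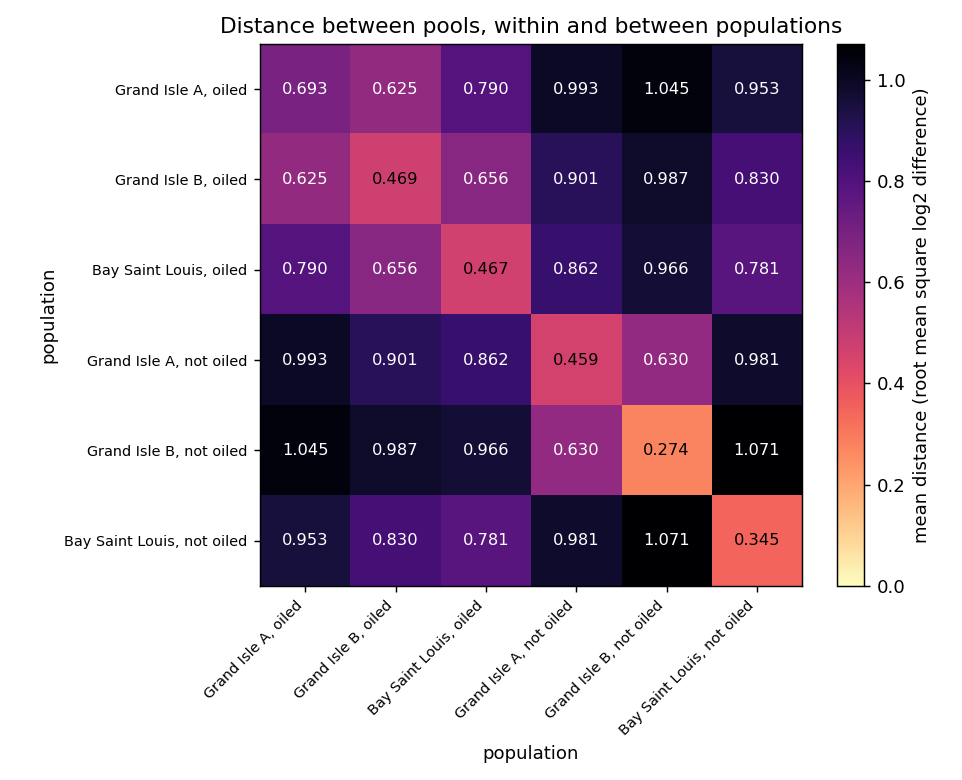
Mean root mean square log2 difference between pools over 14988 probes, for each pair of populations (both axes), with the mean between pools of 1 population on the diagonal. The shortest distances between populations are 0.625 between the oiled and 0.63 between the not oiled populations of the Grand Isle sites, and the longest is 1.071.

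The main question of the design was which transcripts differ between oiled and not oiled populations when the 3 within-site differences are averaged. In limma with Benjamini-Hochberg adjustment 8383 probes (55.9%) passed, 4178 higher and 4205 lower in oiled populations. Most of these differences were small, with a median of 0.48 on the log2 scale, and 1171 probes differed at least 2-fold. Of the 8383 probes, 5222 (62.3%) had the same sign at all 3 sites, 2646 higher and 2576 lower. Selection for a large mean favours like signs. Over all tested probes 41.7% had the same sign at the 3 sites, against 25% for 3 independent sites. The 2 Grand Isle effects correlated with each other (r = 0.68 across probes), so this excess does not by itself show a likeness with Bay Saint Louis. A smaller group of 642 probes passed at each of the 3 sites in 1 direction, 367 higher and 275 lower in the oiled population, while 631 passed alike at both Grand Isle sites and in the opposite direction at Bay Saint Louis.

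The probes with the largest differences of like sign at the 3 sites were carried mainly by Grand Isle. CUST_4982_PI428634872 (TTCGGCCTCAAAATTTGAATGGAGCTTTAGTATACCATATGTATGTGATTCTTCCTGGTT) was higher by 7.11 ± 1.27 on the log2 scale (SE, adjusted p = 0.000298), and only 1 of the 9 not oiled pools had it well above background. Its limited fold was 70, which is not a strict lower bound, since dim not oiled pools of site A kept their own signal. Only 1 of 3 oiled Bay Saint Louis pools had it above background, and the difference there did not pass (3.38 ± 2.2, SE, adjusted p = 0.274). CUST_3271_PI428634872 (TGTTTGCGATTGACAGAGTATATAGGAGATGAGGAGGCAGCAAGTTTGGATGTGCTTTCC) was higher by 5.07 ± 0.6 (SE, adjusted p = 7.42e-06) and passed at all 3 sites, at 4.88, 6.62 and 3.71. CUST_6272_PI428634872 (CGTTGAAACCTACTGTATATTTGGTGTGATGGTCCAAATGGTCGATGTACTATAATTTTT) changed by -5.43 ± 0.42 (SE, adjusted p = 1.37e-07), and passed at all 3 sites. Its limited fold was 21.1, in which dim oiled Bay Saint Louis pools kept their own signal. It was well above background in no oiled Grand Isle pool, so it was at least 29.1-fold lower at site A and 36.8-fold lower at site B; at Bay Saint Louis, with 1 of 3 oiled pools well above background, the difference was -3.13. CUST_1639_PI428634872 (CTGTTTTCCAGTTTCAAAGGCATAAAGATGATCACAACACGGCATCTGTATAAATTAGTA) changed by -4.21 ± 0.17 (SE, adjusted p = 2.01e-10), from -5.54 and -6.46 at Grand Isle, while its difference at Bay Saint Louis, -0.63, did not pass (adjusted p = 0.121). None of the 4 passed in the additive fit with slide, where CUST_4982 was at -0.12, CUST_3271 at 0.49, CUST_6272 at -3.63 and CUST_1639 at -3.82 (adjusted p = 0.995, 0.957, 0.693 and 0.719).

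The normexp background correction gave 4756 probes for oil over 3 sites. Pools of 1 population share a place, so the adjusted p-values measure the spread between pools and not the spread between oiled marshes. With the 6 population means as the units and site as a block, limma called 0 probes, with 2394 at an unadjusted p under 0.05. No slide held both oil states of 1 site. An additive fit of site and oil called 6589 probes, and 2 with slide added as a fixed block. The median standard error with slide was 0.441, against 0.097 in the fit of 6 population means, and the oil values of these fits correlated at r = 0.53 across probes, which are not independent replicates.

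Each site was then taken alone. At Grand Isle site A 6950 probes passed, 3343 higher and 3607 lower in the oiled population, and 2268 of them differed at least 2-fold. CUST_4982_PI428634872 was higher by 8.1 ± 2.2 (SE, adjusted p = 0.00805), with 1 of 3 not oiled pools well above background. It did not pass with slide as a fixed block (1.45, adjusted p = 0.919), with array weights (6.52, adjusted p = 0.12) or without pools 2 and 12 (6.58, adjusted p = 0.0715). CUST_1558_PI428634872 was higher by 7.81 ± 0.25 (SE, adjusted p = 2.55e-11), at least 56.6-fold. CUST_518_PI428634872, well above background in 1 of 3 oiled pools, changed by -8.42 ± 0.3 (SE, adjusted p = 6.9e-11), and CUST_519_PI428634872 by -7.69 ± 0.32 (SE, adjusted p = 5.01e-10), at least 75-fold. With slide as a fixed block, which could be fitted for this site through a chain of slides, 394 probes passed and 94.9% of the 6950 kept their sign. With only these 2 populations in the fit 3761 passed, and with normexp 3027. Fits of only the 2 populations compared gave 7759 at site B and 4413 at Bay Saint Louis, so site A then had the fewest calls. The main counts rest on 1 spread shared by all populations. The median SD between pools was 0.269 in the oiled population of site A and 0.088 in the not oiled one of site B.

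At Grand Isle site B 6787 probes passed, 3359 higher and 3428 lower in the oiled population, with 2420 at least 2-fold different. With normexp 3267 passed. CUST_15553_PI428634872 was higher by 9.74 ± 0.24 (SE, adjusted p = 1.76e-12), at least 259-fold, and was not well above background in the not oiled population of site B, while its differences at Bay Saint Louis and site A were 0.84 and -0.08. CUST_4982_PI428634872 was higher by 9.84 ± 2.2 (SE, adjusted p = 0.00217), at least 415-fold. CUST_2998_PI428634872 changed by -10.65 ± 1.66 (SE, adjusted p = 0.000125), and CUST_10496_PI428634872 by -7.05 ± 0.34 (SE, adjusted p = 2.03e-09). Here slide and population cannot be told apart, since a fit with slide as a fixed term and 6 population means leaves this difference without an estimate.

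The effects at the 2 Grand Isle sites resembled each other. Across probes they correlated at r = 0.68 (rho = 0.7), and 4487 probes passed at both sites, of which 4340 (96.7%) went in 1 direction. Of these, 2123 were higher at both sites, against 749.2 for independent lists, and 2217 were lower, against 825. The 2 sites share no pools, but slide 1 held the oiled pools of site A and 1 oiled pool of site B. How much of the likeness comes from a shared slide was not tested.

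At Bay Saint Louis 4076 probes passed, 2206 higher and 1870 lower in the oiled population, with 1105 at least 2-fold different. CUST_11168_PI428634872 was higher by 9.53 ± 0.62 (SE, adjusted p = 3.69e-07), at least 244-fold, while it was lower at both Grand Isle sites (-2.37 and -2.1). CUST_9626_PI428634872 was higher by 9.1 ± 2.09 (SE, adjusted p = 0.00553), at least 155-fold, and also higher at site B (8.58, adjusted p = 0.00389). CUST_6661_PI428634872 changed by -8.28 ± 0.91 (SE, adjusted p = 3.26e-05), at least 162-fold, and CUST_4644_PI428634872 by -7.5 ± 1.25 (SE, adjusted p = 0.000676), at least 53.5-fold. CUST_4644 was also lower at site A (-5.23, adjusted p = 0.00349), while CUST_6661 was higher at site B (2.84, adjusted p = 0.02). None of these probes passed at the other Grand Isle site. Slide and population cannot be told apart for this site's oil difference in a fit with 6 population means. The normexp background correction reduced the count to 1607, with 37.4% of them higher in place of 54.1%, and array weights raised it to 6865.

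The Bay Saint Louis effect did not follow that of Grand Isle. It correlated at r = 0.05 (rho = 0.1) with site A and r = 0.03 (rho = 0.05) with site B across probes. Of 2009 probes called at both Bay Saint Louis and site A 52.1% went in 1 direction, and of 2002 called at both Bay Saint Louis and site B 50.5% did. Of the 4340 probes called alike at both Grand Isle sites, 3067 (70.7%) were not called at Bay Saint Louis, 642 were called in the same direction and 631 in the opposite one. Among all tested probes 27.2% were called at Bay Saint Louis, so the 70.7% is not particular to these probes.

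**Figure D3:**
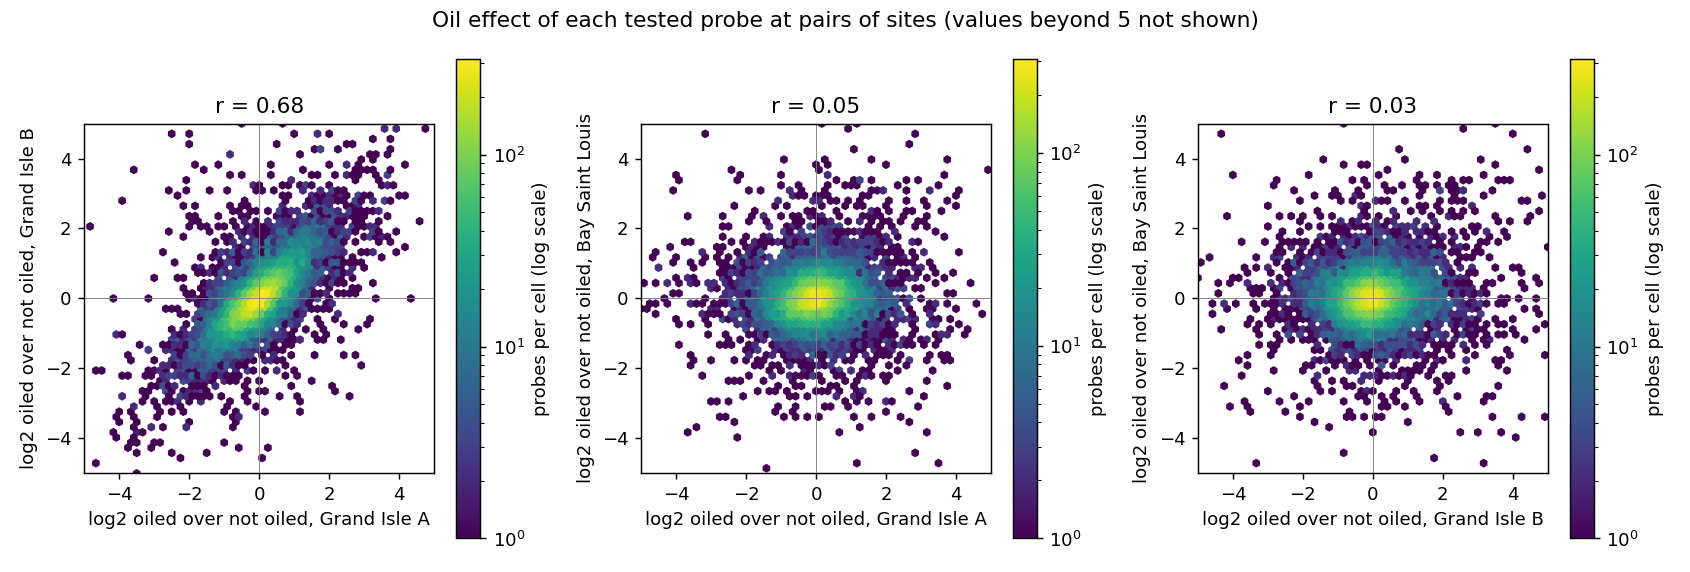
Log2 difference between the oiled and the not oiled population at pairs of sites, with the shade giving the number of probes per cell on a log scale; the axes end at 5 in each direction. The 2 Grand Isle sites lie along a diagonal (r = 0.68), and Bay Saint Louis shows no trend with site A (r = 0.05) or site B (r = 0.03).

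Whether the oil difference depended on the site was tested directly with a moderated F test over the 3 within-site differences, and 6549 probes (43.7%) passed, or 2616 with normexp. The 4 probes with the largest F that also passed in opposite directions at different sites had the same arrangement, with the 2 not oiled Grand Isle populations on one side and the other 4 on the other. CUST_13913_PI428634872 had log2 differences of -4.05 at site A, -3.3 at site B and 1.21 at Bay Saint Louis (F = 471, adjusted p = 1.65e-10). CUST_15947_PI428634872 had -6.22, -5.06 and 0.7 (F = 470, adjusted p = 1.65e-10), and CUST_14687_PI428634872 had -6.14, -5.08 and 1.01 (F = 438, adjusted p = 2.16e-10). CUST_1558_PI428634872 went the other way, with 7.81, 7.9 and -1.09 (F = 432, adjusted p = 2.16e-10), where the Grand Isle values are at least 5.82 and 6.15 as lower bounds. Its level was -8.23 ± 0.41 and -8.59 ± 0.08 in the not oiled Grand Isle populations, where it was not well above background, and between -1.65 ± 0.52 and -0.43 ± 0.02 in the other 4 (SD, n = 3 each).

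**Figure D4:**
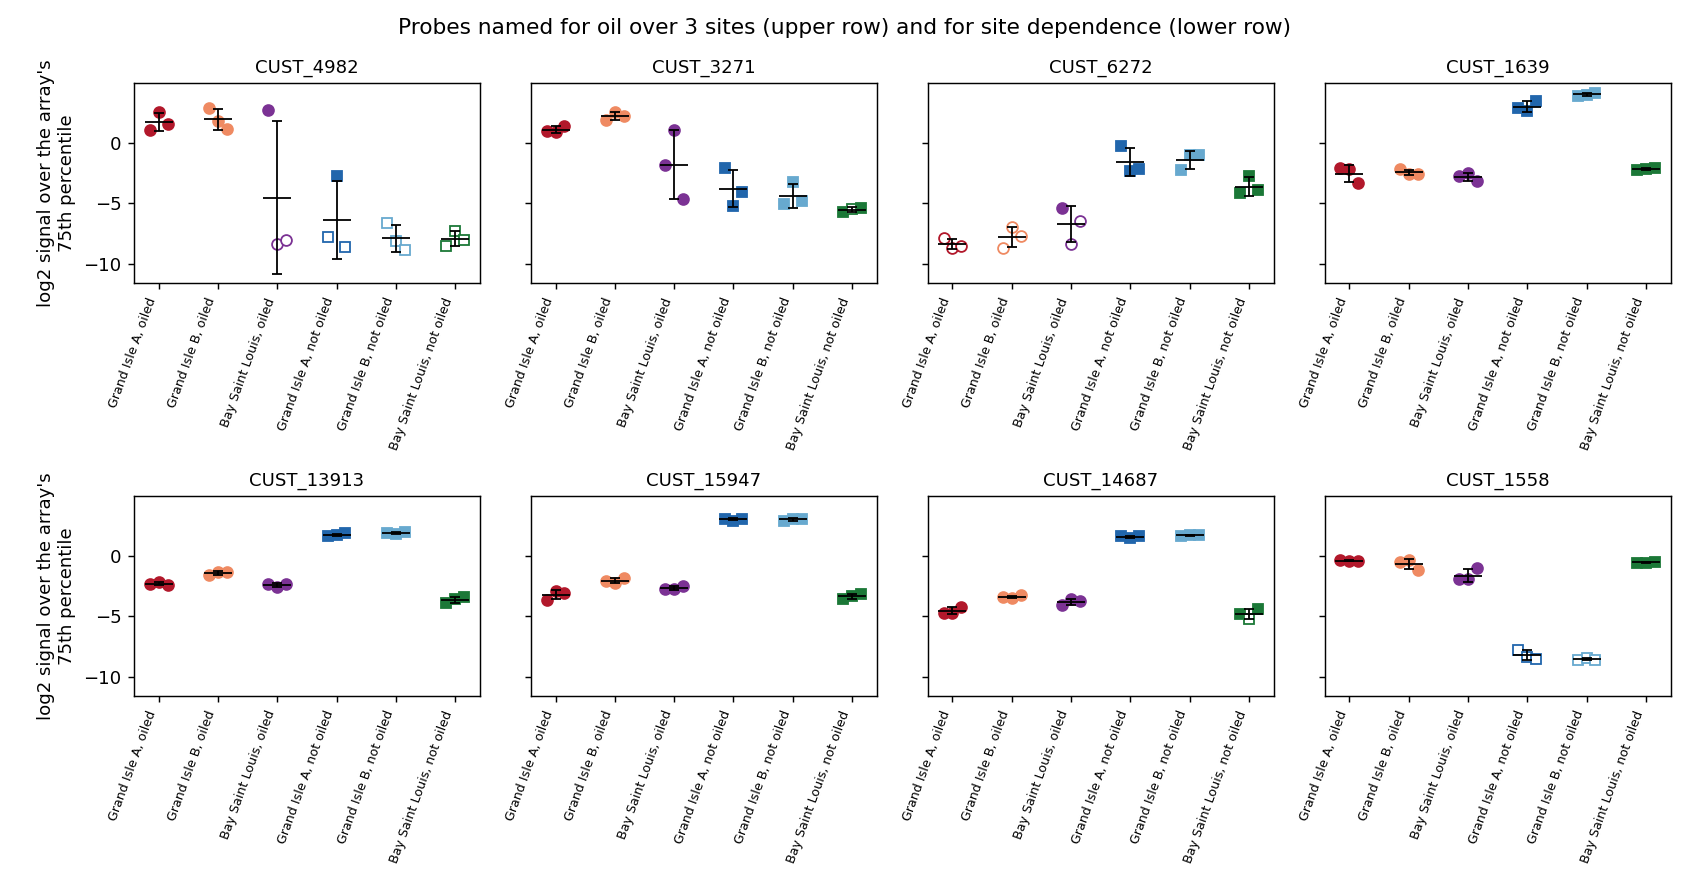
Log2 signal over the array's 75th percentile (vertical axis) in each pool of the 6 populations (horizontal axis) for the 4 probes named for oil over 3 sites (upper row) and the 4 named for site dependence (lower row); open points are pools in which the probe was not well above background, and bars are the mean ± SD (n = 3). In the lower row the not oiled Grand Isle populations stand apart from the other 4, and CUST_4982 in the upper row is bright in 1 of the 3 oiled Bay Saint Louis pools.

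Sites were compared with oil balanced over the contrast. Between Bay Saint Louis and Grand Isle 6914 probes passed, 3329 higher (48.1%) and 3585 lower at Bay Saint Louis. The balance depended on the background correction, since normexp gave 3105 probes with 65.2% higher. CUST_529_PI428634872 was higher there by 4.22 ± 0.58 (SE, adjusted p = 4.46e-05), with a limited fold of 10.4. CUST_9840_PI428634872 was higher by 4.04 ± 0.98 (SE, adjusted p = 0.00374), with a limited fold of 12.5 on average. In both, dim oiled Grand Isle pools kept their own signal, so these folds are not strict lower bounds. CUST_9840 owed its difference to the not oiled population of Grand Isle site B (-8.45, in 0 of 3 pools well above background) and 1 of 3 oiled pools of site A. Its means in the not oiled population of site A (0.67) and the oiled population of site B (0.23) lay near those of Bay Saint Louis (1.25 oiled, 1.81 not oiled). CUST_2998_PI428634872 changed by -7.35 ± 1.01 (SE, adjusted p = 4.48e-05), although the oiled population of site B (-4.84) lay near the oiled one of Bay Saint Louis (-4.99), and CUST_10246_PI428634872 by -7.25 ± 1.39 (SE, adjusted p = 0.000679), at least 45.5-fold. With slide as a fixed additive block 284 probes passed, and the values correlated with those without the block at r = 0.88. CUST_9840 (5.82, adjusted p = 0.236), CUST_2998 (-10.37, adjusted p = 0.103) and CUST_10246 (-5.8, adjusted p = 0.276) kept their direction but did not pass in that fit. Within slide 2 the difference between oiled Bay Saint Louis and oiled Grand Isle site B pools (2 and 2 pools) correlated at r = 0.63 across probes with the same difference from pools on other slides. Within slide 4, 3042 probes differed at least 2-fold between 1 not oiled Bay Saint Louis pool and 3 of Grand Isle site B.

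The 2 Grand Isle sites differed much less, with 626 probes past the test, 337 higher and 289 lower at site A. This count ranged from 281 without pool 14 to 1119 without pool 1, and normexp gave 69, with 68.1% higher in place of 53.8%. The share higher was 45.4% under quantile normalization and 47.2% without pool 1, so which direction prevailed depended on the setting. Slide as a random block raised it to 2257, and array position as a covariate lowered it to 389. The named probes mostly marked 1 population. CUST_9492_PI428634872 (4.49 ± 0.12, SE, adjusted p = 5.24e-12, at least 11.8-fold) and CUST_15553_PI428634872 (4.41 ± 0.17, SE, adjusted p = 1.09e-09, at least 11.7-fold) were below background in the not oiled population of site B and well above it in the other 5. CUST_8613_PI428634872 (-3.42 ± 0.26, SE, adjusted p = 4.78e-06, limited fold 5.56) was well above background in that population alone, and did not pass with normexp (-1.03, adjusted p = 0.516). CUST_3921_PI428634872 changed by -3.03 ± 0.67 (SE, adjusted p = 0.0212), with a limited fold of 4.39 in which a dim oiled pool of site A kept its own signal. It did not pass with normexp (-0.42, adjusted p = 0.822) or without pool 4, 11, 13, 14 or 15. No probe passed with slide as a fixed additive block, where the values correlated with those without it at r = 0.47 and CUST_15553 (-0.5) and CUST_8613 (0.5) reversed. Within slide 1, the only one with pools of both sites, 540 probes differed at least 2-fold between 3 oiled pools of site A and 1 of site B. The root mean square of this difference was 0.48. Pools within the oiled populations of sites A and B lay 0.693 and 0.469 apart on average. The count of 540 therefore does not tell a site difference from the spread between pools.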

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

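The tests of slide, of foreign RNA and of exchanged labels were chosen after the results they measure had been seen; those of noise between pools, of single slides and of other splits were set before.

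The oil difference depended on the site for 6549 probes in the test of that dependence (2616 with normexp). The largest difference between sites was -5.26 on the log2 scale for CUST_13913_PI428634872, -6.92 for CUST_15947_PI428634872, -7.15 for CUST_14687_PI428634872 and 8.99 for CUST_1558_PI428634872 (at least 7.25, since it was not well above background in the not oiled population of site B), each between a Grand Isle site and Bay Saint Louis. Of 100 splits that exchanged pools between oil states within sites, the real one gave the highest count and the highest other gave 1778. The other splits mix pools of different populations, so the real one is favoured whenever populations differ, for whatever reason. These splits do not address chance differences between populations.

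The 4 named probes set the not oiled Grand Isle populations apart from the others. In a contrast of the mean of these 2 populations with the mean of the other 4, chosen after the pattern had been seen, 8738 probes passed, 1790 of them at least 2-fold different. In both populations 287 probes were at least 2-fold higher and 280 at least 2-fold lower than in each of the others, and 30 probes were at least 8-fold higher and 7 at least 8-fold lower, where the background limits low values. A slide effect is argued against: the shortest distance between such a pool and a pool of another population on its own slide exceeded the longest distance between the 2 populations, which lay on different slides, by 0.16. Foreign RNA in these leaves is argued against as the whole cause, since 53.6% of the probes past the test and at least 2-fold different were lower there, where added RNA would dilute the rest alike. A state of the not oiled Grand Isle marshes, whether from the absence of oil or from another feature of those places, stays open and was not tested.

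The oil effect at Bay Saint Louis was unlike that at Grand Isle. Noise between pools is argued against, because effects from disjoint sets of Bay Saint Louis pools correlated at a mean r of 0.78 over 9 ways of dividing them (0.72 to 0.83). Effects of single slides are argued against by r = 0.73 between the effect from slides 2 and 4 and that from slides 3 and 5; a difference shared by slides 2 and 3 against 4 and 5 is not excluded. Exchanged labels of the 2 Bay Saint Louis populations would reverse the sign of r with the mean Grand Isle effect, which was 0.05. An r this small lies near 0 under either labelling, so it cannot tell whether the labels were exchanged. A difference between sites in exposure, habitat or plant genotype stays open and was not tested.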

How the results depend on the processing

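Of the values of named probes recomputed under other settings, 793 of 837 kept their direction and side of the threshold, 38 kept the direction only and 6 reversed. The named probes were extremes that passed in the main fit, and many settings only left out 1 pool. A high share was therefore favoured in advance and does not measure robustness. On population means all 4 oil probes kept the direction only. In the additive fits with slide 8 values kept the direction only and 3 reversed. Quantile normalization, median centring, both filters on dim probes and the trended robust prior left all 7 counts within 1.5 times. Under quantile normalization 8064 of the 8383 oil calls remained in the same direction. The normexp correction gave 4756 probes for oil over 3 sites, 3027 at site A, 3267 at site B, 1607 at Bay Saint Louis, 2616 for site dependence, 3105 between Bay Saint Louis and Grand Isle (65.2% higher, against 48.1%) and 69 between the Grand Isle sites (68.1% higher, against 53.8%). The authors' values with columns as named gave 1668, 2679, 1, 0, 0, 0 and 1 in that order. CUST_2998_PI428634872 (0.33, Bay Saint Louis against Grand Isle), CUST_15553_PI428634872 (-0.22) and CUST_3921_PI428634872 (1.95, both site A against B) reversed there, where the columns hold other samples' arrays and the table has empty cells. With each of the 16 matching columns taken as the array it equals, chosen after seeing the data, the counts were 8463, 6639, 7091, 4311, 6998, 6910 and 687. CUST_2998_PI428634872 was then at -6.56. These columns kept their empty cells, so empty cells are argued against as the cause of the low counts and of this reversal. The 2 columns that equal no array were left out. The other reversed probes had no value, and the cause of their reversal was not tested. Scanner values without pools 2 and 12, also chosen after seeing the data, left all 7 counts within 1.5 times.

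For oil over 3 sites the additive fit with slide gave 2 probes, population means 0 (2394 at an unadjusted p under 0.05) and the test against 1.5-fold 977. CUST_4982_PI428634872 reversed with slide (-0.12, adjusted p = 0.995). Site A gave 3761 with only its populations in the fit and 394 with slide as a block; the additive fit with slide gave 284 between Bay Saint Louis and Grand Isle, where 3 of the 4 named probes no longer passed, and 0 between the Grand Isle sites, where CUST_15553_PI428634872 (-0.5) and CUST_8613_PI428634872 (0.5) reversed. These slide fits for sites were chosen after seeing the data. Fits of only the 2 populations compared gave 7759 at site B and 4413 at Bay Saint Louis. Array weights gave 5569 at site A, 9476 at site B and 6865 at Bay Saint Louis. The order of the sites by count therefore depended on how the spread was estimated. Slide as a random block, with a correlation of -0.17 between arrays of a slide, raised the Grand Isle site comparison to 2257, and array position lowered it to 389. The causes were not tested. In 20 simulations without a slide effect the additive fit with slide called 0 to 48 probes when the fitted site dependence was kept, a range that holds the 2 observed, and 295 to 424 when it was left out. The fitted means can themselves hold slide effects, so this excludes nothing about slide. The additive fit without slide gave 6589 on the data. Leaving out each pool gave 7792 to 8766 for oil over 3 sites, 5724 to 7130 at site A, 5577 to 7468 at site B, 2805 to 4887 at Bay Saint Louis, 5445 to 7384 for site dependence, 5961 to 7310 between Bay Saint Louis and Grand Isle, and 281 to 1119 between the Grand Isle sites. Only the last moved by over 1.5 times, without pool 1 (1119), 11 (378), 13 (323), 14 (281) or 15 (342). CUST_3921_PI428634872 no longer passed without pool 4, 11, 13, 14 or 15. Gene list tests and their alternatives were not run, since no probe has a name. Signal near background limits the folds given as lower bounds.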

Other observations

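The tests of the value table's columns were chosen after the result had been seen.

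Pools of oiled populations varied more than those of not oiled ones at each site. The median SD between pools was 0.269, 0.177 and 0.169 in the oiled populations of Grand Isle sites A and B and Bay Saint Louis, and 0.172, 0.088 and 0.129 in the not oiled ones, ratios of 1.56, 2.02 and 1.31. Over the 6 populations the difference did not pass (exact permutation test, two-sided p = 0.2, smallest possible 0.1). This test did not keep the pairing by site, so it does not measure the differences within sites. In the oiled population of Grand Isle site A 74 probes were at least 8-fold higher in 1 pool than in both others, against 10 in the not oiled population of that site, while 19 and 20 were at least 8-fold lower in 1 pool.

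Some probes were present in whole populations and below background in others. At Grand Isle site A 66 probes were well above background in all oiled and no not oiled pools and 49 the reverse; at site B these numbers were 101 and 127, and at Bay Saint Louis 100 and 40. No probe separated all 9 oiled from all 9 not oiled pools in this way (0 in each direction), while 17 were above background in both not oiled Grand Isle populations alone, 7 in the other 4 populations alone and 2 in both oiled Grand Isle populations alone.

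The oil count also reflects which population carries which label. With the oil label exchanged at Bay Saint Louis, the same model called 7686 probes, close to the 8383 with the real labels, while exchanging it at Grand Isle site A or B gave 2128 and 2432. Of 100 splits of pools within sites, 1, the real one, reached 8383 and the highest other gave 1387. The other splits mix pools of different populations, so the real one is favoured whenever populations differ, for whatever reason. Chance differences between populations are not addressed by these splits. For the single sites the 10 possible splits are too few for a share under 0.05, and the real one alone (1 of 10) gave the most: 6950 at site A (highest other 8), 6787 at site B (highest other 2) and 4076 at Bay Saint Louis (highest other 1). Between Bay Saint Louis and Grand Isle 1 of 100 splits, the real one, reached 6914 and the highest other gave 123. Between the Grand Isle sites 4 of 100 splits reached 626, the real one included, a share under 0.05, although the highest other, 1385, exceeded the real count.

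The headings of the authors' value table may be displaced. Listed by scanner file, 16 of the 18 arrays have their nearest neighbour in their own population, and listed by the table's headings 2 of the 18 columns do. The first count argues against scanner files attached to wrong samples at random, but an exchange of labels between whole populations would not show in it. The columns headed for pools 17 and 18 equal no array and come nearest to those of pools 2 and 12, with median absolute differences of 0.0529 and 0.127. That they are repeat arrays of those pools is a hypothesis that was not tested.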
